A study of Mus musculus with 9 samples.

How the data were processed

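Gene expression was measured in the hippocampus of 9 male ICR mice, 8 weeks old, with 1 array per mouse and 3 mice in each of 3 groups: vehicle (1% Tween 80), 1% LA and 10% LA. Per the labels' protocols, mice were randomly allocated, LA was given by whole-body inhalation for 7 days, the tail suspension test followed 30 min of inhalation, RNA was extracted with an organic solvent reagent, and biotin-labelled material was prepared from 100 ng of total RNA with a whole-transcript kit. Groups and replicate numbers were taken from the sample titles, which match the source names and the growth protocol.

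The labels conflict in part. The description field of 5 samples (the 3 vehicle samples and 1% LA replicates 1 and 2) tells of oral dosing with saline or oleacein and an injection of saline or LPS, a bacterial endotoxin, and 3 of the 5 name LPS. The series' design text names human cells, oleacein and the human version of the array. The transcript clusters are those of the mouse array, and no group was taken from either text. Which of these statements applied to a mouse was checked only through inflammatory gene levels, given in the closing section.

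The deposited signal table holds log2 signals per transcript cluster, which the authors normalized with signal space transformation robust multi-chip analysis, per the series' design text and the submitters' processing notes. Those sources name Transcriptome Analysis Console 4.0.2 and limma. The deposited comparison tables hold the authors' log2 group averages, which are not the plain means of the 3 arrays, and signed linear folds of treated over vehicle, with a fold below 1 given as minus its inverse, per the file headers and the values. They also hold each cluster's p-value and FDR p-value from the authors' one-way analysis with an empirical Bayes correction, per the series' design text. The deposited series matrix holds log2 values per probe set, normalized by the authors, and its columns follow those of the signal table for 8 arrays. The third vehicle column does not, with r = 0.981 and 1778 clusters more than 1 log2 unit apart, against at most 1 such cluster for each other array. Which of its columns belongs to that sample is not given in the sources used here. The medians of the 9 series matrix columns lay between 6.82 and 6.96. The genome build is not given in the sources used here, so no genome positions are printed. A table of mouse gene names made for assembly GRCm38.p6 served only to match older symbols and to find neighbouring genes.

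Of 22206 clusters in the signal table, 22203 had a gene symbol in the file, 21367 of them 1 symbol and 836 several. Clusters with several symbols entered the tests and are not named, and 27 symbols that a spreadsheet had turned into dates were restored from the gene descriptions in the file. Clusters were kept where the mean log2 signal over the 9 arrays lay above the 40th percentile (5.98), which left 13321. Values were used as deposited. The moderated test of limma 3.58.1 (R 4.3.3) was run on 1 fit of all 9 arrays with a mean per group, and p-values were adjusted by the Benjamini-Hochberg method over the clusters kept, with a threshold of 0.05. Errors of log2 differences are limma's unscaled standard errors times each cluster's moderated SD. No replicate block entered the fit. The count by the submitters' criteria took an unadjusted p under 0.05 and a linear fold above 2. The number of arrays, 3 per group, limits the precision, and the median standard error of a log2 difference was 0.21.

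Before the data were examined, 28 functional and 17 cell type or region marker lists were fixed, with 1123 of 1124 symbols found on the array. Lists with at least 5 members kept were tested with limma's camera at a preset correlation of 0.01, adjusted over the 45 lists. Camera with an estimated correlation and fry were run beside it. No list call held with an estimated correlation, and fry called 0 lists at 1% LA, 2 at 10% LA (immediate early genes, and hypoxia and glycolysis at adjusted p = 0.0229) and 1 between the doses. Within groups, members followed the mean of the others at median correlations of 0.838 (myelin), 0.790 (microglia), 0.741 (granule cells) and 0.317 (immediate early genes). Where members vary together, camera's p-values at the preset correlation do not measure the spread of a list between mice. Adjustment over the list alone means Benjamini-Hochberg over that list's members, for lists fixed before the data were examined.

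Genes are named by a rule fixed at the same time. Where fewer than 10 genes passed in a direction, as at both doses, the 10 with the largest log2 difference were taken among those with an unadjusted p under 0.05 whose treated and vehicle values did not overlap, and 3 per direction between the doses. Predicted genes, receptors of smell and taste and histone genes were counted and not named. Of each list discussed, members past the threshold over the list alone are named, in 1 list as examples, or else up to 4 with the smallest p. Of the choroid plexus markers at 1% LA, all of which passed, the 8 that the first part of the rule took are named. Htr2c and Gfra2 were named because they passed over the list alone in lists that were not shifted, and Shank1 and Shank3 likewise. Cwc22 was chosen after its values were seen.

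The agreement of the doses was set against 100 simulated draws of unchanged groups that share a simulated vehicle group. Genes were drawn independently there, each with the same SD in every group. The same steps were tested on simulated data with 200 changed genes among 13321, in 20 runs per comparison. For 1% LA against vehicle the test recovered 6.50% of genes changed 1.5-fold, 47.8% of those changed 2-fold and 86.8% of those changed 3-fold, with 5.25 false calls per run. For 10% LA against vehicle these shares were 7.00%, 51.6% and 83.6%, and between the doses 7.10%, 46.2% and 84.9%. A shift of 0.25 log2 given to the immediate early genes was called in 19 of 20 runs and a shift of 0 in none. Genes were drawn independently in all these runs. They therefore do not show how often camera calls lists whose members vary together, as those of the real arrays do.

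The alternatives fixed in advance were no filter or a filter at the 60th percentile, quantile normalization on top, series matrix values, each array left out in turn, array weights, the replicate number as a block, a trended and robust prior, fits of the compared groups alone, 1 cluster per gene and a minimum fold of 1.2. After the data were seen, 3 were added: both LA groups together against vehicle, the choroid plexus level of each array as a covariate, and series matrix values without the first vehicle array. Figures were drawn with matplotlib 3.10.9.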

Results

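Hippocampal RNA of 9 male ICR mice, an outbred strain, was measured on Clariom S arrays, with 1 array per mouse. For 7 days the mice inhaled either the vehicle, 1% Tween 80, or linalyl acetate (LA), a fragrant ester of lavender and bergamot oils, at 1% or at 10%, with 3 mice in each of the 3 groups. The tail suspension test, a measure of immobility under an inescapable stress, followed 30 min of inhalation. The values are log2 signals of 13321 transcript clusters above a low-signal filter. Over all clusters, those below the filter included, the median log2 signal of an array lay between 6.84 and 6.88. The third vehicle array differed between the 2 tables of values deposited for the series: its columns correlated at r = 0.981 across clusters, against at least 0.9993 for each of the other 8 arrays. The main values, and those of single genes unless stated otherwise, come from the signal table. Values from the series matrix are marked as such.

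The first comparison asked what inhaling 1% LA did to hippocampal expression. Immediate early genes, which neurons transcribe within minutes of activity, were lower than in vehicle mice. Arc, a regulator of synaptic strength (transcript cluster TC1500001712.mm.2), had a mean log2 signal of 7.33 ± 0.29 (SD, n = 3) at 1% LA against 8.79 ± 0.40 (SD, n = 3) in vehicle, a log2 difference of -1.46 (SE 0.23). Of the 28 immediate early genes kept by the filter, from 35 on the array, 9 fell when adjusted over the list alone and none rose. None passed over all genes tested. Beside Arc these were the transcription factors Junb (-1.29, SE 0.26), Nr4a1 (-1.19, SE 0.28), Nr4a2 (-1.31, SE 0.38) and Egr3 (-0.76, SE 0.23). The others were the kinase Sik1 (-0.97, SE 0.20), the phosphatase Dusp1 (-1.52, SE 0.51), the matricellular protein gene Cyr61 (-0.997, SE 0.22) and Ier5 (-1.17, SE 0.33). Over the list alone 8 of the 28 fell in the series matrix. The mean shift of the list was -0.53 log2 with the signal table and -0.44 with the series matrix, and camera called it lower in both (adjusted p = 1.5e-07 and 1.2e-07). The call was lost at adjusted p = 0.49 with an estimated correlation, and with the choroid plexus level as a covariate the mean was -0.27 (adjusted p = 0.036). Egr1, a further member of the list, had a log2 difference of -1.32 (SE 0.48) that missed the threshold over the list alone, and of -0.68 with series matrix values.

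Markers of the choroid plexus, the epithelium that secretes cerebrospinal fluid and lies against the hippocampus, were higher at 1% LA. All 21 markers kept by the filter, of 25 on the array, rose when adjusted over the list alone, with a mean of 2.68 log2. None passed over all genes tested. Ttr, the thyroxine carrier of the cerebrospinal fluid (TC1800000158.mm.2), stood at 19.53 ± 0.11 (SD, n = 3) against 13.73 ± 4.72 (SD, n = 3) in vehicle, a log2 difference of 5.80 (SE 1.74). Its level at 1% LA was close to the highest signal of any cluster (19.85 to 19.93 per array), which limits how exactly the difference can be read. The potassium channel genes Kcnj13 (4.64, SE 1.13) and Kcne2 (2.93, SE 0.89), the anti-ageing factor gene Kl (3.94, SE 0.91) and Enpp2, which encodes autotaxin (3.73, SE 1.00), were among these markers. The same held for the folate receptor gene Folr1 (3.56, SE 1.12), Clic6 (3.53, SE 1.05) and the clotting factor gene F5 (3.20, SE 0.57). Camera gave adjusted p = 6.9e-19 for the list, and adjusted p = 0.50 with an estimated correlation. The vehicle mice differed widely from one another, with Ttr at 10.42, 19.13 and 11.63 in the 3 arrays. In the series matrix the third vehicle array held Ttr at 19.53, none of the 21 markers passed over the list alone, and the mean shift was 1.42 log2 with adjusted p = 9.8e-09. With the first vehicle array also left out the shift was 0.36 log2 (adjusted p = 0.20).

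Beside choroid plexus, 6 of the gene lists fixed in advance stood higher at 1% LA by camera. Markers of oligodendrocyte precursors shifted by 0.44 log2 (adjusted p = 0.00066). Of its 13 members, Olig1 (1.21, SE 0.33), Olig2 (0.65, SE 0.22), Lhfpl3 (0.96, SE 0.31) and the extracellular matrix gene Tnr (0.59, SE 0.21) rose when adjusted over the list alone, and none did in the series matrix. Genes of cholesterol synthesis shifted by 0.24 log2 (adjusted p = 0.012), with no member passing alone. Sqle (0.74, SE 0.20), Hmgcs1 (0.74, SE 0.24), Nsdhl (0.58, SE 0.21) and Sc5d (0.63, SE 0.23) had the smallest p-values in that list. Genes of thyroid hormone and retinoid transport shifted by 0.78 log2 (adjusted p = 0.0095). Members that rose over the list alone included Ttr, the retinol receptor gene Stra6 (1.38, SE 0.27) and the thyroid hormone transporter gene Slco1c1 (1.14, SE 0.32), and none passed in the series matrix. Ttr is also in the choroid plexus list. Microglial markers shifted by 0.33 log2 (adjusted p = 0.0057), where P2ry13 (0.62, SE 0.23), Olfml3 (0.59, SE 0.23), Csf1r (0.61, SE 0.26) and Tmem119 (0.47, SE 0.21) missed the threshold over the list alone. Markers of dentate gyrus granule cells shifted by 0.31 log2 (adjusted p = 0.012), of which Rfx3 (0.78, SE 0.20) rose over the list alone, though not in the series matrix, and C1ql2 (0.79, SE 0.24), C1ql3 (0.90, SE 0.28) and Maml2 (0.36, SE 0.23) did not pass. Meningeal and fibroblast markers shifted by 0.56 log2 (adjusted p = 0.027), with Igf2 (2.99, SE 1.00), Ogn (1.09, SE 0.38), Islr (1.11, SE 0.39) and Dcn (1.35, SE 0.60) short of the threshold over the list alone. With the choroid plexus level as a covariate all 6 calls ended (adjusted p = 0.14, 0.078, 0.51, 0.999, 0.79 and 0.39 in the order given), the meningeal mean turned to -0.21 and Igf2 to -0.69, and in the series matrix without the first vehicle array the mean was -0.0932. Every 1% LA array lay above every vehicle array in the choroid plexus level (0.943 to 1.94 against -2.22 to 0.275). At 1% LA this covariate therefore cannot separate that level from treatment. With an estimated correlation the adjusted p was 0.49 for the precursor, cholesterol and transport lists and 0.86 for the microglial, granule cell and meningeal lists. With series matrix values the transport, microglial, granule cell and meningeal lists were not shifted (adjusted p = 0.053, 0.15, 0.55 and 0.56). In that table oligodendrocyte and myelin markers, at 0.18 with the signal table (adjusted p = 0.32), were lower by a mean of -0.30 (adjusted p = 0.00068). Without the first vehicle array the cholesterol, transport, granule cell and meningeal calls were lost (adjusted p = 0.11, 0.19, 0.11 and 0.57), and without the third the microglial and granule cell calls (adjusted p = 0.085 and 0.10). The granule cell call was also lost without 1% LA replicate 1 or 3 (adjusted p = 0.32 and 0.056), the meningeal call without replicate 1 or 2 (adjusted p = 0.15 and 0.12), and the cholesterol call without replicate 2 (adjusted p = 0.12). Over the alternatives the granule cell mean ranged from 0.00776 to 0.52 and the meningeal mean from -0.21 to 1.14.

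Outside these lists, Rxfp1, a relaxin receptor gene of pyramidal cells, had a log2 difference of -1.63 (SE 0.48) at 1% LA, and Rspo2, which encodes a Wnt signalling enhancer, one of -1.46 (SE 0.34). Values for Rgsl1 (-1.54, SE 0.39), the synaptic organizer genes Cbln1 (-1.44, SE 0.43) and Nxph3 (-1.24, SE 0.28) and the postsynaptic scaffold gene Shank3 (-1.27, SE 0.39) lay in the same range. Over the alternatives these genes kept their direction but differed in size. Rxfp1 ranged from -1.90 to -0.48, Rspo2 from -1.65 to -0.77 and Rgsl1 from -1.99 to -0.87. The ranges were -1.83 to -0.41 for Cbln1, -1.43 to -0.52 for Nxph3 and -1.56 to -0.86 for Shank3. Lbp, which encodes a lipopolysaccharide binding protein, had a difference of 2.80 (SE 0.92), of 1.22 with series matrix values and of -0.42 with the choroid plexus level as a covariate. The clock output gene Dbp (0.94, SE 0.17), Clock (0.64, SE 0.16) and the nuclear receptor gene Rorb (0.90, SE 0.30) rose and the Dbp antagonist gene Nfil3 fell by 0.66 (SE 0.19) when adjusted over the 18 members of the circadian clock list alone. The list as a whole was not shifted (mean 0.06, adjusted p = 0.75). In the series matrix the clock list shifted by 0.21 log2 (adjusted p = 0.032), and Dbp and Nfil3 passed over the list alone while Clock and Rorb did not. Of the 20 genes taken by the naming rule at 1% LA, 13 had differences over 1.5 times larger in the signal table than in the series matrix: 8 of choroid plexus, Igf2, Lbp, Rxfp1 (-1.08 in the matrix), Rgsl1 (-0.87) and Egr1.

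No single gene passed limma's test at 1% LA: 0 of 13321 clusters had an adjusted p under 0.05, the smallest was 0.356, and 1589 (843 higher and 746 lower) had an unadjusted p under 0.05. The submitters' criteria, an unadjusted p under 0.05 and a fold above 2, kept 188 clusters (141 higher and 47 lower), against 32 with series matrix values. The authors' deposited table listed 0 clusters under a false discovery rate of 0.05, a smallest rate of 0.444 and 320 clusters past the same criteria. That table covers 22206 clusters, and without the filter 215 clusters met the criteria here. The 3 treated and 3 vehicle values did not overlap in 1924 clusters (14.4%, where chance gives 10%). Without the first vehicle array 222 clusters passed (149 higher and 73 lower) and 481 met the criteria, and Arc and Rgsl1 were among those that passed. Without the second 1 passed (Ttr), and without the third 0 passed and 113 met them.

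**Figure D1:**
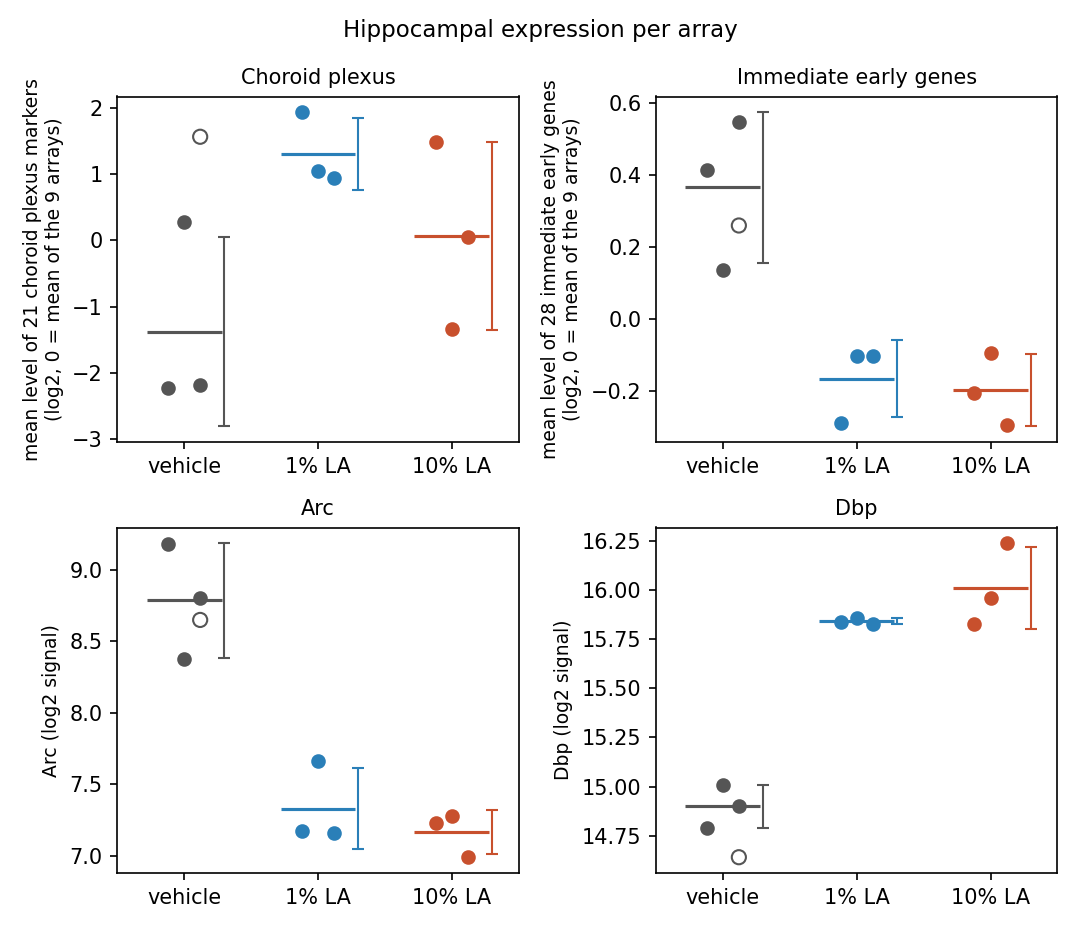
Levels per array of choroid plexus markers, immediate early genes, Arc and Dbp in log2 units, for vehicle, 1% LA and 10% LA mice (n = 3 each). Filled points are arrays in the signal table, horizontal lines group means, bars the SD, and the open circle the third vehicle array in the series matrix. For Arc, the 3 vehicle arrays lay between 8.38 and 9.18 and all 6 LA arrays between 6.99 and 7.66.

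The second comparison asked the same of 10% LA. Immediate early genes were again lower than in vehicle mice: 13 of the 28 fell when adjusted over the list alone, none rose, and 0 passed over all genes tested. Arc stood at 7.17 ± 0.16 (SD, n = 3) against 8.79 ± 0.40 (SD, n = 3), a log2 difference of -1.62 (SE 0.23) with limma's adjusted p = 0.191. Dusp1 (-1.79, SE 0.51), Egr1 (-1.30, SE 0.48), Junb (-1.29, SE 0.26), Cyr61 (-1.26, SE 0.22), Nr4a1 (-1.23, SE 0.28), Nr4a2 (-1.14, SE 0.38) fell in the same way. So did Egr3 (-0.78, SE 0.23), Egr2 (-0.74, SE 0.23), the stress-induced factor Atf3 (-0.70, SE 0.20), Jun (-0.68, SE 0.23), Sik1 (-0.65, SE 0.20) and the DNA damage response gene Gadd45b (-0.52, SE 0.17). In the series matrix 9 of the 28 fell over the list alone. The mean shift was -0.56 log2 with the signal table and -0.45 with the series matrix (adjusted p = 2.8e-07 and 7.8e-07 by camera). It had an adjusted p = 0.54 with an estimated correlation, while fry, which tests the list without reference to other genes, gave 0.0458.

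Microglial markers shifted by 0.52 log2 at 10% LA (adjusted p = 3.1e-06), by 0.31 with series matrix values (adjusted p = 0.0004) and by 0.29 without 10% LA replicate 1 (adjusted p = 0.0041). Of 22 members 5 rose over the list alone: the purinergic receptor genes P2ry12 (1.62, SE 0.44) and P2ry13 (0.80, SE 0.23), the colony stimulating factor receptor gene Csf1r (0.91, SE 0.26), the complement gene C1qb (0.97, SE 0.31) and Olfml3 (0.92, SE 0.23). None did in the series matrix. Markers of oligodendrocyte precursors shifted by 0.40 log2 (adjusted p = 0.0017), with Olig1 (1.36, SE 0.33), Enpp6 (0.75, SE 0.17) and the proteoglycan gene Vcan (0.62, SE 0.20) rising over the list alone. In the series matrix Olig1 and Vcan rose over the list alone, and Sox10 fell (-0.67, and -0.39 with the signal table). Oligodendrocyte and myelin markers shifted by 0.57 log2 (adjusted p = 8.0e-06): Tspan2 (1.12, SE 0.28) rose over the list alone, though not in the series matrix, and Trf (1.13, SE 0.37) and Mog (0.88, SE 0.30) missed that threshold. Astrocyte markers shifted by 0.23 log2 (adjusted p = 0.046), with Aqp4 (0.86, SE 0.31), the gap junction gene Gja1 (0.69, SE 0.24), Mlc1 (0.59, SE 0.24) and Clu (0.58, SE 0.23) not passing alone. Choroid plexus markers shifted by 1.44 log2 (adjusted p = 9.9e-07) with 0 of 21 passing over the list alone. The smallest p-values in the list were those of F5 (1.77, SE 0.57), Ttr (4.42, SE 1.74), Cab39l (0.96, SE 0.39) and Enpp2 (2.39, SE 1.00), and Ttr differed by 1.70 with series matrix values. Without the second vehicle array the choroid plexus mean was 2.27, and without 10% LA replicate 1 it was 0.73. With an estimated correlation the adjusted p was 0.75 for each of these 5 lists. With series matrix values the choroid plexus list shifted by 0.19 log2 (adjusted p = 0.56), the myelin list by 0.08 (adjusted p = 0.47), the astrocyte list by 0.08 (adjusted p = 0.39) and the precursor list by 0.20 (adjusted p = 0.054). Heat shock and chaperone genes, at -0.16 with the signal table (adjusted p = 0.061), were lower by a mean of -0.21 there (adjusted p = 0.0032). The choroid plexus mean turned to -0.87 and the myelin mean to -0.0787 in the series matrix without the first vehicle array. The myelin mean was 0.28 without the third vehicle array (adjusted p = 0.0040). The astrocyte call was also lost without the first or the third vehicle array (adjusted p = 0.11 and 0.34), 1% LA replicate 1 (adjusted p = 0.051) or 10% LA replicate 1 (adjusted p = 0.097), and with the choroid plexus level as a covariate (adjusted p = 0.38).

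Of the other genes taken by the naming rule, the log2 differences at 10% LA were largest for the phospholipase gene Pla2g7 (1.65, SE 0.39), the imprinted noncoding RNA Kcnq1ot1 (1.60, SE 0.44), Xkr4 (1.56, SE 0.42), the metallothionein gene Mt2 (1.42, SE 0.38) and Pigz (1.37, SE 0.33). They were followed by Ehd3 (1.35, SE 0.33), Dbpht2 (1.33, SE 0.33), the creatine synthesis gene Gatm (1.31, SE 0.27) and the DNA demethylase gene Tet2 (1.30, SE 0.31). On the lower side Shank3 (-1.62, SE 0.39) and Shank1 (-1.22, SE 0.31), which encode scaffolds of the postsynaptic density, fell when adjusted over the 28 members of the postsynaptic density list alone, and neither passed in the series matrix. That list was not shifted as a whole (mean -0.18, adjusted p = 0.19). The complement protease gene Masp2 (-1.48, SE 0.61) and H2-Ke6 (-1.20, SE 0.36) had differences of similar size. Of the 20 genes taken by the naming rule, 7 had differences over 1.5 times larger in the signal table than in the series matrix: Kcnq1ot1 (0.77 in the matrix), Xkr4 (0.91), Pigz (0.85), Olig1 (0.73), Gatm (0.64), Tet2 (0.79) and H2-Ke6 (-0.75). Dbp (1.11, SE 0.17) and Clock (0.65, SE 0.16) rose over the clock list alone, in the series matrix Dbp and not Clock, and Nfil3 (-0.52, SE 0.19) and Rorb (0.79, SE 0.30) did not pass. The authors' deposited table gave folds of -2.89 for Arc and 2.13 for Dbp at 10% LA, and of -3.08 and 1.92 at 1% LA. At 1% LA it gave 354 for Ttr and 29.1 for Enpp2, against 55.7 and 13.3 from the group means used here.

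Limma called 0 of 13321 clusters at 10% LA, with 1853 (905 higher and 948 lower) at an unadjusted p under 0.05, and the authors' deposited table listed 0 under a false discovery rate of 0.05, with a smallest rate of 0.267. The submitters' criteria kept 145 clusters (103 higher and 42 lower), against 24 with series matrix values and 343 in the authors' deposited table. The deposited table covers 22206 clusters, and without the filter 157 clusters met the criteria here. The 3 treated and 3 vehicle values did not overlap in 1948 clusters (14.6%, where chance gives 10%). Without the first vehicle array 533 clusters passed (299 higher and 234 lower) and 519 met the criteria. All 10 genes named on the higher side and Shank3, Arc, Junb, Cyr61 and H2-Ke6 were then among those that passed. Without the second, 3 passed (Cyr61, Arc and Ttr) and 12 lists were shifted. Without the third, 0 passed and 78 met the criteria, and without 10% LA replicate 2 the criteria kept 394 and 10 lists were shifted. With series matrix values and without the first vehicle array 0 clusters passed at either dose.

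**Figure D2:**
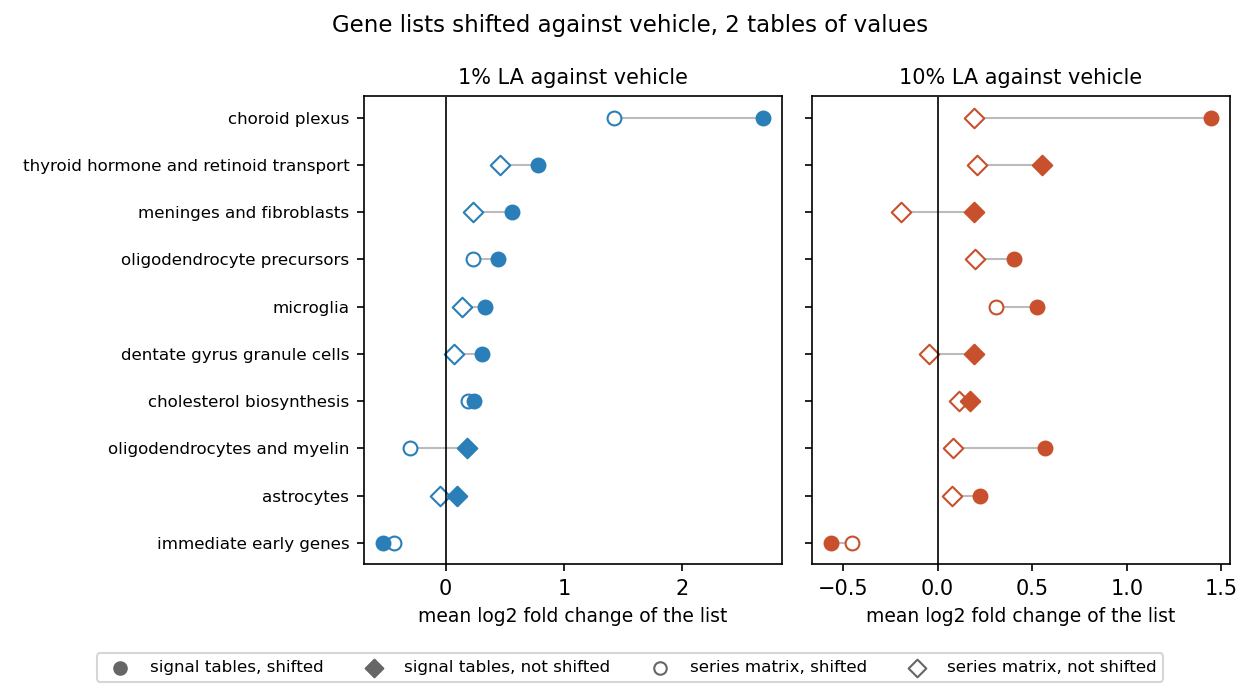
Mean log2 fold change of the 10 gene lists that camera called at 1% or 10% LA against vehicle (3 arrays per group). Filled symbols are signal table values and open symbols series matrix values; circles are calls at an adjusted p under 0.05 and diamonds are not. Immediate early genes lay between -0.56 and -0.44 at both doses in both tables, while choroid plexus markers lay between 0.19 and 2.68.

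Several lists fixed for their relation to mood, stress and odour were not shifted at either dose in either table. Glucocorticoid response genes had mean differences of 0.01 log2 at both doses (adjusted p = 0.96 and 1.00), and the inflammatory response list of 0.17 and 0.15 (adjusted p = 0.57 and 0.50). Genes of serotonin signalling had means of 0.36 and 0.32 (adjusted p = 0.069 and 0.066). The serotonin receptor gene Htr2c (1.87, SE 0.44), which choroid plexus also expresses, rose over the list alone at 1% LA, though not in the series matrix, while Htr4 (0.73, SE 0.33), Htr5a (0.30, SE 0.18) and Maob (0.25, SE 0.22) did not pass. For neurotrophin and growth factor signalling the means were 0.17 and 0.05 (adjusted p = 0.60 and 0.90), with Gfra2 (1.07, SE 0.26) rising over the list alone at 1% LA. The 1470 clusters named as olfactory or vomeronasal receptors had a median log2 signal of 4.52 against 6.85 for all clusters, 0 passed limma's test, and 99 and 86 had an unadjusted p under 0.05 (6.73% and 5.85%, against 9.52% and 10.7% of all clusters). Between the doses it was 70 of these receptors (4.76%, against 2.75% of all clusters).

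The third comparison set 10% against 1% LA. Choroid plexus markers were lower at the higher dose by a mean of -1.24 log2 over 21 members (adjusted p = 1.3e-11). Steap1 (-1.70, SE 0.55), F5 (-1.43, SE 0.57), Tmem72 (-1.13, SE 0.51) and Kl (-1.99, SE 0.91) had the smallest p-values in the list, and no member passed over the list alone. Oligodendrocyte and myelin markers were higher by 0.38 log2 (adjusted p = 5.6e-08), with the smallest p-values in Aspa (0.54, SE 0.21), Tspan2 (0.65, SE 0.28), Ppp1r14a (0.64, SE 0.27) and Cnp (0.49, SE 0.27). Genes of the unfolded protein and integrated stress response were lower by a mean of -0.22 (adjusted p = 0.00014; Dnajc3 at -0.54, SE 0.19, Herpud1 at -0.45, SE 0.22, Creld2 at -0.42, SE 0.20 and Ddit3 at -0.34, SE 0.18). Heat shock and chaperone genes were lower by a mean of -0.18 (adjusted p = 0.0012), among them Hspa1a (-0.52, SE 0.17), Chordc1 (-0.40, SE 0.22) and Dnajb1 (-0.39, SE 0.23). Genes of hypoxia and glycolysis were lower by a mean of -0.14 (adjusted p = 0.018, fry 0.0370), among them Ankrd37 (-0.49, SE 0.21), Ldhb (-0.47, SE 0.29), Vegfa (-0.26, SE 0.17) and Pdk1 (-0.24, SE 0.18). Microglial markers (mean 0.19, adjusted p = 0.0088) and astrocyte markers (mean 0.13, adjusted p = 0.012) were higher, with C1qb (0.72, SE 0.31), Itgam (0.42, SE 0.21) and Ppp1r3c (0.40, SE 0.19) among those with the smallest p-values. Meningeal markers were lower (mean -0.37, adjusted p = 0.00996), with Mgp at -0.62 (SE 0.29) and Igf2 at -1.79 (SE 1.00). With an estimated correlation the smallest adjusted p of the lists was 0.76. With the choroid plexus level as a covariate the stress response, heat shock, hypoxia and meningeal calls ended (adjusted p = 0.21, 0.059, 0.071 and 0.96). The LA arrays are nearly the same in both tables, so the series matrix, which gave the same 8 calls, is no separate test of them.

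Of single genes with an unadjusted p under 0.05 and values that did not overlap, Pigz (1.08, SE 0.33), the adhesion receptor gene Adgrd1 (0.86, SE 0.20) and Rnd3 (0.84, SE 0.24) had the largest positive differences between the doses. Steap1, the progestin receptor gene Paqr8 (-1.10, SE 0.25) and the biliverdin reductase gene Blvra (-0.82, SE 0.23) had the largest negative ones. Limma called 0 of 13321 clusters, 271 had an unadjusted p under 0.05, and 831 did not overlap between the doses (6.24%, where chance gives 10%). Without 10% LA replicate 2 the number of shifted lists was 4, and the stress response, heat shock, meningeal and hypoxia calls were lost (adjusted p = 0.11, 0.063, 0.85 and 0.11). The choroid plexus mean was -0.53 without that array (adjusted p = 0.020) and -1.95 without 10% LA replicate 1, where the myelin mean was 0.24. Without 10% LA replicate 1 the microglial mean was -0.04 (adjusted p = 0.94), the stress response mean was -0.36, and the astrocyte and hypoxia calls were lost (adjusted p = 0.26 and 0.053). Leaving out 1% LA replicate 1 ended the microglial and meningeal calls (adjusted p = 0.13 and 0.31), replicate 2 the astrocyte and hypoxia calls (adjusted p = 0.065 for both), and replicate 3 the same pair (adjusted p = 0.051 and 0.089).

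The fold changes of the 2 doses against vehicle resembled each other across genes. They correlated at r = 0.83 (jackknife SE 0.14) over 13321 clusters, which are not independent replicates, and 81.0% had the same sign. Unchanged groups simulated with a shared, simulated vehicle group gave r = 0.50 and 66.6%. The covariance was 0.116 against a simulated 0.0292, a difference of 0.0868, and with series matrix values r was 0.65. The simulation drew genes independently and gave every group the same spread. In the arrays genes vary together, and Ttr had an SD of 4.72 in vehicle against 0.11 and 1.86 at 1% and 10% LA. The gap to the simulated values therefore cannot decide whether the doses share a response. Of the clusters past the submitters' criteria, 41 were higher at both doses and 23 lower at both, where independent lists would share 1.09 and 0.148, and part of the excess may come from the shared vehicle arrays. Arc and Dbp differed in the same direction at both doses, and with both LA groups together against vehicle their log2 differences were -1.54 (SE 0.20, limma adjusted p = 0.0879) and 1.03 (SE 0.14, adjusted p = 0.103). In that comparison, added after the data were seen, 0 clusters passed limma's test and 2295 had an unadjusted p under 0.05. A moderated F test over the 3 groups also called 0, with a smallest adjusted p of 0.34 and 1331 at an unadjusted p under 0.05, while 99 passed without the first vehicle array and 1 without the second.

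**Figure D3:**
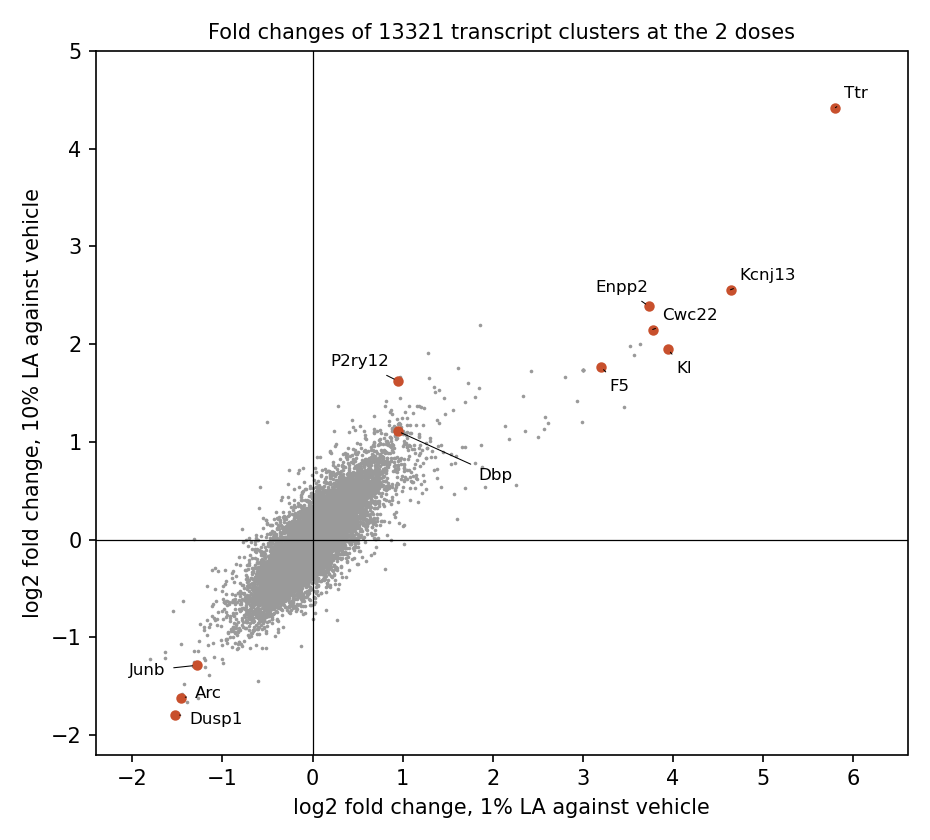
Log2 fold changes of 13321 transcript clusters at 1% LA (horizontal) and 10% LA (vertical) against the same 3 vehicle arrays, 1 point per cluster, with named genes in colour. Choroid plexus genes lie far along the diagonal, with Ttr at 5.80 and 4.42, and Arc lies at -1.46 and -1.62.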

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

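The choroid plexus list and its comparison with series matrix values were fixed before the data were examined. The use of that comparison to weigh causes, and all other tests in this part, were chosen only after the results were seen. The third vehicle column of the series matrix, which the main values leave out, held signals above the level of the vehicle arrays used. Choroid plexus markers there had a mean level of 1.57 log2 above the mean of the 9 arrays used, against at most 0.275 in the 3 vehicle arrays used. Cwc22 had a log2 signal of 13.71 against at most 7.42. The mean level of oligodendrocyte and myelin markers was 0.649 against at most 0.155.

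For the difference between the 2 columns of the third vehicle array, another normalization of the same array was excluded: their median absolute difference was 0.339 log2, against at most 0.059 for the other 8 arrays. An exchange of 2 arrays of the series was excluded too, since the signal table column correlated with every series matrix column at no more than 0.989, where the other arrays matched at 0.9993 or more. An array of another sample in 1 of the tables fitted, since the 2 columns correlated at 0.981 and different arrays of the series at 0.980 to 0.993. The design gives no biological explanation, and none was tested. Which of the columns belongs to the vehicle mouse stayed open.

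The rise of choroid plexus markers was weighed against the same column and against dissection. With the series matrix values the shift was 1.42 log2 (SE 1.16) at 1% LA, where the column as a cause cannot be told apart from an effect of LA. At 10% LA it was 0.192 (SE 1.16), against 1.44 (SE 0.98) with the signal table, so the column as a cause fitted by the rule used. With that column left out of the signal table and not replaced, the shifts were 2.28 at 1% LA and 1.04 at 10% LA. The fall to 0.192 therefore depends on the array put in its place, and leaving the column out does not end the shift. Differing amounts of choroid plexus left on the dissected hippocampi also fitted: within groups each marker followed the mean of the others at a median correlation of 0.946, against at most 0.498 for 1000 random lists, and the vehicle arrays ranged from -2.22 to 0.275 log2. An effect of LA on choroid plexus remains a hypothesis that these arrays do not separate from dissection.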

How the results depend on the processing

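The alternatives were planned, except both LA groups together against vehicle, the choroid plexus level as a covariate and the series matrix values without vehicle replicate 1, which were chosen only after the results were seen. All 46 named gene differences kept their direction with quantile normalization, array weights and series matrix values. This was largely set by the naming rule, which took genes whose group values did not overlap in these arrays. Array weights cannot reverse such a difference, and the series matrix holds nearly the same values for all arrays but the third vehicle array. Other filters, a trended prior, 1 cluster per gene, the 2 groups alone and a fold minimum leave such differences as they are and made no call among them. Of 22 list calls, 22 were kept under quantile normalization, 21 with no filter, 19 above the 60th percentile, 17 with array weights and 14 with series matrix values. Those 14 were 4 of 8 calls at 1% LA, 2 of 6 at 10% LA and 8 of 8 between the doses. The LA arrays are nearly the same in both tables, so the last 8 were not separately tested. With series matrix values the submitters' criteria kept 32 clusters at 1% LA and 24 at 10% LA, the doses correlated at r = 0.65, and 3 lists were shifted at 10% LA. Array weights raised the criteria count at 10% LA to 329. An estimated correlation left 0, 0 and 0 lists at 1% LA, 10% LA and between the doses, and fry 0, 2 and 1. With the choroid plexus level as a covariate 3 lists were shifted at 1% LA, 8 of 19 list calls were kept and 10 lost, and at 1% LA Igf2 (-0.69), Lbp (-0.42) and the meningeal list (-0.21) reversed. The choroid plexus list and its members have no value in that setting. At 1% LA, where every array lay above vehicle in that level, the setting cannot separate the level from treatment. With series matrix values and without vehicle replicate 1 the criteria kept 47 and 57 clusters, 2 lists were shifted at 1% LA, and of 22 list calls 11 were kept and 8 lost. The 22 include the 8 calls between the doses, whose arrays that setting leaves nearly the same. There the lists of meninges at 1% LA (-0.0932), choroid plexus at 10% LA (-0.87) and oligodendrocytes and myelin at 10% LA (-0.0787) reversed. The cause of these changes was not tested.

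When each array was left out in turn, genes changed ranged from 0 to 222 at 1% LA and 0 to 533 at 10% LA, both highest without vehicle replicate 1, and stayed at 0 between the doses. Genes differing among the 3 groups ranged from 0 to 99, and clusters past the criteria from 113 to 481 and from 78 to 519. The lists shifted ranged from 5 to 9, 5 to 12 and 4 to 11, and r between the doses from 0.72 to 0.89. The microglial mean between the doses ranged from -0.0445 (without 10% LA replicate 1) to 0.39 (without 10% LA replicate 2). Of 198 list values 170 kept their call and 27 lost it. Apart from the smaller number of arrays, the cause of these changes was not tested. The replicate block, fitted although the labels do not say what the replicate numbers share, gave 0, 0 and 0 genes changed, 193 and 145 clusters past the criteria and 8, 7 and 9 lists. Deviations of arrays with the same number correlated between -0.169 and 0.168, which shows no strong pairing by number and, with 3 arrays per group, cannot exclude one. Clusters with low signal, under the filter at 5.98 log2, were not tested, among them Fos (5.96, 5.41 and 5.42 in vehicle, 1% LA and 10% LA) and Npas4 (5.59, 4.18 and 4.16).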

Other observations

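The camera tests of lists, the series matrix values as an alternative, the test of the description field and the splits of the arrays were planned. The other tests in this part, among them those of explanations for the immediate early genes and Cwc22, were chosen only after the results were seen. Genes of GABA signalling were not shifted as a list (mean 0.16 log2 at 1% LA and 0.17 at 10% LA, adjusted p = 0.28 and 0.21). Of its 23 members Gabra2, a receptor subunit gene, had log2 differences of 1.04 (SE 0.34) and 1.17 (SE 0.34), and Slc6a11, an astrocytic GABA transporter gene, of 0.55 (SE 0.19) and 0.69 (SE 0.19), with none passing over the list alone. Cngb1, a subunit gene of a cyclic nucleotide-gated channel, rose over the list of olfactory signalling at both doses (0.69, SE 0.18, and 0.96, SE 0.18), and the muscarinic receptor gene Chrm4 fell over the cholinergic list at 1% LA (-0.86, SE 0.21). Trpm3, which choroid plexus also expresses, rose over the TRP channel list at 1% LA, to 15.09 ± 0.52 (SD, n = 3) from 12.59 ± 1.28 (SD, n = 3). With series matrix values none of Cngb1, Chrm4 and Trpm3 passed. These genes were picked after their values were seen.

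Markers of pyramidal cells and interneurons were not shifted by camera. CA1 markers had means of -0.03 and -0.14 log2 at 1% and 10% LA (adjusted p = 0.86 and 0.36), CA2 and CA3 markers of -0.02 and -0.06 (adjusted p = 0.86 and 0.82) and interneuron markers of -0.05 and -0.04 (adjusted p = 0.94 and 0.93). Among interneuron markers Calb2 (0.95, SE 0.24) rose over the list alone at 1% LA, though not in the series matrix. Endothelial markers had means of 0.07 and 0.08 (adjusted p = 0.86 and 0.73). Of their 20 members the lipid transporter gene Mfsd2a (1.11, SE 0.34) and Itm2a (1.04, SE 0.24) rose and the receptor gene Flt1 fell by 0.66 (SE 0.18) over the list alone at 10% LA, and with series matrix values Flt1 alone did. All of these genes were picked after their values were seen.

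A lower level of immediate early genes in mice that inhaled LA is the hypothesis these arrays leave most open to follow-up: all 3 vehicle arrays lay above all 6 LA arrays in both tables, with an exact p = 0.0119, the smallest that 84 splits allow, and 0.268 and 0.536 after adjustment over 45 lists. The tables differ only in the third vehicle array, so the second is no separate test. Oligodendrocyte precursors had the same unadjusted exact p with the signal table, and 0.0476 with the series matrix. The cholesterol and transport lists had 0.0238 each with the signal table. The other lists called against vehicle stayed above 0.05 there: choroid plexus 0.0595, microglia 0.0833, granule cells 0.190, astrocytes 0.214, myelin 0.226 and meninges 0.238. Lists that camera did not call also lay under 0.05: antioxidant response and serotonin signalling at 0.0357 each, and olfactory signalling and synaptic vesicle genes at 0.0476 each. A low exact p was thus not particular to the lists called. For the immediate early genes the array in the third vehicle column was excluded as the cause, since the difference was -0.445 log2 (SE 0.083) with series matrix values against -0.548 (SE 0.104) with the signal table. With the choroid plexus level as a covariate the difference was -0.402 (SE 0.107). At 10% LA, where that level overlapped vehicle, it was -0.425 (SE 0.095) against -0.564 without the covariate. This argues against differing amounts of choroid plexus as the whole cause at 10% LA. At 1% LA it shrank to -0.274 (SE 0.122) from -0.532. There the covariate cannot separate the level from treatment, so a part of choroid plexus in the difference stays open. Killing the LA mice at another time of day cannot be told apart from an effect of LA. Dbp differed by 1.03, while 8 clock genes that rise and fall with it had a mean difference of -0.0529 with the signal table. With series matrix values it was 0.221. The standard errors of these means, 0.0807 and 0.110, were taken over the 8 genes and do not measure the spread between mice.

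The description fields of vehicle replicate 3 and of 1% LA replicates 1 and 2 named a lipopolysaccharide injection that titles and source names did not. The inflammatory list gave no sign that these 3 mice had received it. In mean standardized level, 3 of the 3 lay below the highest of the other 6 arrays (-0.657, 0.191 and -0.290 against up to 0.553). Only 10 of the 40 members passed the filter, so members with low signal did not enter, and the levels cannot exclude an injection. In the series matrix the mean log2 level of the third vehicle array was 0.098 in place of -0.356, below 0.323 in the highest of the other 6.

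Cwc22 varied within groups more than all but 1 of the genes (SD 2.73, median of all genes 0.263), from 6.30 to 14.34 over the arrays, and 7 predicted genes beside it, 6 of which hold identical values and so are not separate measurements, varied in the same way. The hypothesis of an inherited copy number that differs between these outbred mice fitted, since the 6 nearest named protein coding neighbours, which such a segment would leave out, had a mean correlation of 0.151 with Cwc22. The neighbours were not alike, from -0.435 (Itga4) to 0.601 (Ccdc141) and 0.686 (Ppp1r1c), so the mean leaves the hypothesis open. The first principal component held 39.2% of the variance, with vehicle replicates 2 and 3 at 29.5 and 49.1 and the other 7 arrays between -25.1 and 7.83. The third vehicle array of the series matrix lay at -14.0, among the others.

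The 6 arrays of a comparison split in 10 ways, which are too few for a share under 0.05. For genes changed the real count was 0 at both doses and between the doses (highest other 0, 4 and 1), which all 10 splits reach whatever the data, so that count decides nothing. The real 188 and 145 clusters past the submitters' criteria were reached in 2 and 2 of the 10 splits (highest other 196 and 287), and the real 8, 6 and 8 shifted lists, the last between the doses, in 4, 4 and 4 (highest other 12, 20 and 11). For the test among the 3 groups, the real count was 0 too, which 100 of 100 splits drawn reach whatever the data, and the highest other was 33. At 10% LA a split with 20 shifted lists against 6 points to differences among the arrays that do not follow the groups. It set vehicle replicates 1 and 3 and 10% LA replicate 2 apart, with choroid plexus levels of -2.22, -2.18 and -1.34. Vehicle replicate 2 and 10% LA replicates 1 and 3, on its other side, had 0.275, 1.49 and 0.0598.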
